A study of Mus musculus with 10 samples.

How the data were processed

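Total RNA from mouse ventricles, extracted with Trizol and RNeasy columns, was labelled as biotinylated cRNA and hybridised to Affymetrix arrays, 1 array per extract. The 10 arrays comprised 3 of TM175, 4 of TM180 and 3 of NTG hearts, and 1 array of each genotype carried an extract pooled from 20 hearts. The deposited values are probe set intensities on a linear scale, made by the authors with RMA, which corrects background, normalizes by quantiles and summarises probes; its version was not stated.

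In the deposited table intensities of 1000 or more were written with a point setting off the last 3 digits, so that a value of this size read as a small decimal. This was undone before any test by comparing each value with the digits it was written with and with the other arrays of its probe set. Of 226900 values, 7844 in 1057 probe sets were read in this way, and the largest repaired value was 17346. On data simulated from the repaired values of probe sets with a settled level and written in the same way, 0 of 223650 values were read wrongly, which tests the reading and not the assumption about the mark. For 228 probe sets the level could not be settled, 225 of them among those tested, and their values were kept as written. This repair departed from the rule set before the data were examined, which chose only between linear and log2 scale. Repaired intensities under 1 would have been set to 1, and log2 was taken.

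Of 22690 probe sets 64 controls were set aside, leaving 22626, of which 20380 carried 1 gene symbol, 691 several and 1555 none. Together they stood for 12393 genes. Gene names, lengths and order along chromosomes came from the RefSeq annotation of the mouse genome. The number of arrays limits the precision. Checked on simulated data, the model without covariate called 20.9% of genes changed by 0.5 on the log2 scale in the TM175 comparison, 76.1% of those changed by 1 and 97% of those changed by 2. In the TM180 comparison it called 25.4%, 77.6% and 98.5%, and between the lines 17.9%, 86.6% and 100%. With extract type in the model the shares at 0.5 were 40.3%, 55.2% and 46.3%. Unchanged probe sets called in these simulations numbered 2, 6 and 1 without covariate and 11, 18 and 11 with extract type. Camera called the shifted list and 0 of 24 others. The simulated noise was independent between probe sets, so this did not test false calls among correlated genes. In the real data the estimated correlation reached 0.7 for the interferon list and was 0.468 for the hypertrophy list.

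Log2 intensities were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per genotype and all 10 arrays. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22626 probe sets and called under 0.05. Fold changes are ratios of geometric means with 95% intervals, and means ± SD are of linear intensities. The 3 comparisons were TM175 with NTG, TM180 with NTG and TM180 with TM175. Calls shared by both lines were set beside the number expected for independent lists and beside 100 simulations of unchanged groups against the same controls. Pooled and individual extracts were compared with genotype in the model. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the repair and the plots.

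The 25 gene lists, written from textbook knowledge before the data were examined, covered the hypertrophy and fetal programme, sarcomere and Z disc, calcium handling, extracellular matrix, fatty acid oxidation, glycolysis, citrate cycle and oxidative phosphorylation, ion channels, immediate early genes, heat shock, antioxidant genes, hypertrophic signalling, apoptosis and the interferon response. Further lists held markers of endothelium, fibroblasts, smooth muscle, macrophages, lymphocytes, red blood cells, atria, skeletal muscle and adipocytes, circadian clock genes and sex-linked genes. They were tested with camera at a preset correlation of 0.01, with fry and with camera at an estimated correlation. For each gene the brightest probe set that carried 1 symbol was used, taking sets with a settled level first. Adjustment was over the 25 lists of a comparison.

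The rule for named genes was also written before the data were examined. It named Tpm1, Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Pln and sex-linked genes always, and the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups, with 1 probe set per gene. It added up to 4 called members per list and, where fewer than 5 genes passed, the 5 smallest p-values. Genes named from the model with extract type followed the same rule.

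Alternatives were individual extracts only, extract type as a covariate, replicate number as a block, array weights, renewed quantile normalization, median centring, only probe sets above the median level, only the groups compared, an intensity trend with robust fitting, a fold of at least 1.5, an adjusted p under 0.01, 1 probe set per gene or the mean of a gene's probe sets, an estimated correlation and leaving out each array in turn. Extract type without TM175 array 1, and extract type with an estimated correlation, were chosen after seeing the data. Raw scans were not used here.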

Results

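Ventricular RNA from 2 lines of transgenic mice and from nontransgenic controls (NTG) was hybridised to Affymetrix 3′ expression arrays. Tropomyosin is the coiled-coil protein that lies along the actin filament of the sarcomere, and both lines, TM175 and TM180, carry an alpha-tropomyosin transgene. The series was set up around early stages of mild and severe hypertrophy, and from background knowledge of these lines TM175 is the milder and TM180 the more severe model. There were 3 TM175, 4 TM180 and 3 NTG arrays. Within each genotype 1 array carried a pool of extracts from 20 hearts and every other array carried 1 heart, so that 3 arrays were pooled and 7 were individual. The labels do not say whether a pool also contained the hearts measured alone. Intensities were available for 22626 probe sets after 64 control probe sets were set aside. The median intensity per array ran from 67.8 to 72.0, and log2 intensities of any pair of arrays correlated at 0.963 to 0.995 across probe sets, which are not independent replicates. The precision of every value is limited by the number of arrays.

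The first principal component held 47.5% of the variance and separated the 3 pooled arrays, with scores of 30.08 to 39.76, from the 7 individual arrays, with scores of -31.56 to 2.65. The third, with 13.6%, separated NTG arrays (-21.38 to -16.67) from transgenic arrays (0.90 to 12.72). Since pooled and individual extracts occurred in each genotype, values are given below also with extract type in the model and within each extract type.

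**Figure D1:**
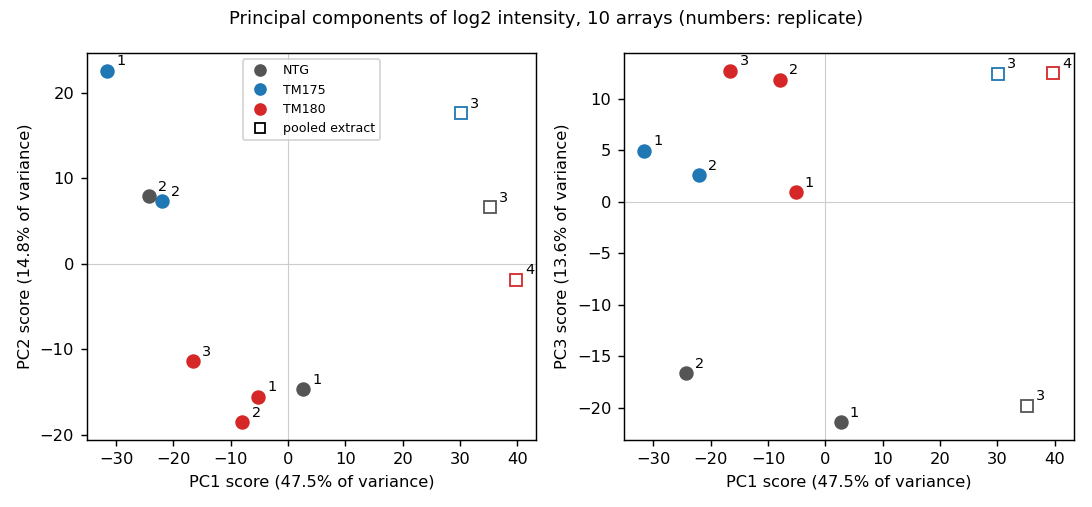
Scores of the 10 arrays on principal components 1 and 2 (left) and 1 and 3 (right) of log2 intensity; colours are genotypes, open squares are pooled extracts and numbers are replicates. The pooled arrays lie at 30.08 or more on component 1, and the NTG arrays lie at -16.67 or less on component 3.

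Tpm1, the alpha-tropomyosin gene from which the transgenes derive, was brighter in every transgenic array than in every control array. Its brightest probe set read 12400, 13200 and 11240 in NTG arrays 1 to 3, 16520, 16170 and 15430 in TM175 arrays 1 to 3, and 16830, 16460, 17350 and 15590 in TM180 arrays 1 to 4. The fold difference was 1.31 in TM175 (95% interval 1.13 to 1.51, adjusted p = 0.173) and 1.35 in TM180 (log2 difference 0.43 ± 0.09 SE, adjusted p = 0.065), so that neither passed the limma test over all probe sets. The log2 difference with extract type in the model was 0.39 in TM175 (adjusted p = 0.0513) and 0.42 in TM180 (adjusted p = 0.0169). A probe set may sum endogenous and transgenic transcripts, and which of these probe sets detect the transgene was not tested. The values do not tell the mutant sequences apart. The brightest Tpm1 probe set held the largest repaired value of all, 17346 in TM180 array 3. Whether intensities this high understated the fold was not tested. Of the remaining Tpm1 probe sets, both dim, 1 had a log2 difference of 0.41 in TM175 and -0.22 in TM180.

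The sex-linked genes differed between arrays of 1 genotype. Xist, the transcript of the inactive X chromosome, read 988 in TM175 array 1 and 99.5 to 136 in the other 6 individual arrays. The pools read 414 in TM175, 394 in TM180 and 149 in NTG. The Y-linked Eif2s3y read 7.23 in TM175 array 1 and 44.7 to 60.8 in the other individual arrays. Xist and Eif2s3y did not pass in any genotype comparison, nor did the Y-linked Kdm5d and Uty (adjusted p of 0.216 to 0.999). The TM175 counts below are therefore also given without TM175 array 1.

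The comparison of TM175 with NTG asked which transcripts differed in the milder line. Myh7, the slow beta-myosin heavy chain of the fetal ventricle, rose 12.8-fold (95% interval 8.27 to 19.7, adjusted p = 0.00164), from 339 ± 12.4 in NTG (SD, n = 3) to 4637 ± 1930 in TM175 (SD, n = 3). Postn, which encodes the matricellular protein periostin, rose 3.14-fold (2.35 to 4.18, adjusted p = 0.0368), from 206 ± 28.8 to 647 ± 110. These 2 probe sets were the limma calls, whereas 2952 probe sets had an unadjusted p under 0.05 and 5361 were called with array weights. Those weights were largest for TM175 array 2 (3.24) and NTG array 1 (2.92), which are single hearts. The next smallest p-values, which did not pass, belonged to Adk, the adenosine kinase gene (1.80-fold lower, adjusted p = 0.111), H2-Aa, an MHC class II chain (2.44-fold lower, adjusted p = 0.111), and Snai1, a zinc-finger repressor (1.53-fold higher, adjusted p = 0.111). Myh7 passed in all 10 fits that left out 1 array. Postn passed in 1 of them, the fit without TM180 array 1, with adjusted p between 0.00875 and 0.247.

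Other cardiac stress genes were scattered in TM175. Nppa, the atrial natriuretic peptide gene, averaged 3274 ± 2520 against 732 ± 151 in NTG, a 3.07-fold difference that did not pass (1.1 to 8.54, adjusted p = 0.35). Its arrays read 521, 5478 and 3822, and without TM175 array 1 and with extract type in the model the log2 difference became 2.70 (adjusted p = 0.000368). That array held the lowest of these values and was left out after seeing the data, so this limma p-value is no separate support. Nppb, the B-type peptide gene, was at 1.21-fold (adjusted p = 0.827), and the skeletal alpha-actin gene Acta1 at 1.02-fold (adjusted p = 0.987). Myh6, the adult alpha-myosin heavy chain, was at 0.887-fold (adjusted p = 0.482). A dimmer Myh6 probe set, widely scattered between arrays, lay at 0.304-fold (0.02 to 4.63, adjusted p = 0.699). Atp2a2, the sarcoplasmic reticulum calcium pump, was at 0.799-fold (0.690 to 0.925, adjusted p = 0.223), and its inhibitor Pln at 0.992-fold (adjusted p = 0.972). Other probe sets, some of unsettled level, lay at 0.785-fold to 0.991-fold for Atp2a2 and at 0.888-fold and 0.93-fold for Pln. None of them passed.

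With extract type in the model, 195 probe sets were called in TM175, 29 higher and 166 lower, including Myh7 and Postn. The individual arrays alone gave log2 differences of 3.53 for Myh7 and 1.59 for Postn and the pooled arrays alone 3.96 and 1.77, and the individual arrays alone had 3 calls. The largest rises after these 2 were the collagen gene Col1a2 (log2 difference 0.95 ± 0.18 SE, adjusted p = 0.0427), the microfibril genes Mfap5 (0.85 ± 0.17) and Mfap4 (0.75 ± 0.15), the secreted glycoprotein gene Fstl1 (0.85 ± 0.16), Pi16 (0.80 ± 0.15) and Dpysl3 (0.68 ± 0.12). By the brightest called probe set of each gene whose arrays did not overlap between the groups, the largest falls were H2-Aa (-1.28 ± 0.18, adjusted p = 0.0243), Pkia, a protein kinase A inhibitor gene (-1.15 ± 0.12, adjusted p = 0.00441), the carboxylesterase gene Ces1d (-1.15 ± 0.18), Rgs2, a regulator of G-protein signalling (-1.1 ± 0.14), and Hccs, the cytochrome c heme lyase gene (-1.07 ± 0.10, adjusted p = 0.00207). Other called probe sets gave -1.67 for H2-Aa, -1.28 for H2-Ab1 and -0.92 for Rgs2. Further falls were in H2-Ab1 (-1.04 ± 0.17), the beta-oxidation thiolase Acaa2 (-1.0 ± 0.20) and Tmod4 (-1.0 ± 0.16). Among these falls the individual arrays alone gave -1.47 for H2-Aa, -0.94 for Pkia and -1.17 for Hccs, and the pooled arrays alone -0.92, -1.58 and -0.87. Without TM175 array 1, an alternative chosen after seeing the data, the same model called 14 probe sets, 4 higher and 10 lower. Myh7, Postn, Pkia, Rgs2 and Hccs were among them, and H2-Aa (adjusted p = 0.0676) and Ces1d (0.0695) were not.

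Of the 25 gene lists, 11 stood apart in TM175 by camera with a preset correlation, 3 higher and 8 lower, and none did with a correlation estimated per list. By fry the matrix (adjusted p = 0.0449), fatty acid oxidation (0.0161), citrate cycle (0.0165) and calcium handling lists (0.0174) passed. The sex-linked (0.0161) and adipocyte lists (0.0492) also passed by fry, though not by camera. The 37 measured extracellular matrix genes had a median log2 difference of 0.49 (adjusted p = 9.1e-12; adjusted p = 0.212 with an estimated correlation). Postn rose among them, 36 of 37 lay above 0, and 12 rose when adjusted over the list alone. The individual arrays gave a median of 0.43 and the pooled arrays 0.49. The 24 fatty acid oxidation genes had a median of -0.29 (adjusted p = 1.69e-08; 0.212 with an estimated correlation), and 12 fell and 1 rose when adjusted over the list alone. Etfdh, the electron-transfer flavoprotein dehydrogenase, was lower by -0.72 ± 0.11 with extract type in the model (adjusted p = 0.0308). The 36 citrate cycle and oxidative phosphorylation genes had a median of -0.21 (adjusted p = 6.19e-11; 0.212 with an estimated correlation), and 6 fell when adjusted over the list alone. For fatty acid oxidation the individual arrays gave -0.28 and the pooled arrays -0.31, and for the citrate cycle list -0.20 and -0.25.

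Smaller shifts in TM175 were those of the sarcomere and Z disc (median -0.12, adjusted p = 0.0204), calcium handling (-0.05, 0.028), glycolysis (-0.11, 0.028), ion channel (-0.17, 0.0352), antioxidant (-0.15, 0.028) and interferon response lists (-0.22, 0.0101). Fibroblast markers (0.26, 0.0271) and lymphocyte markers (0.18, 0.027) stood higher. With an estimated correlation the adjusted p of these 8 lists lay between 0.212 and 0.55. The interferon list had a median of -0.45 in the individual arrays and 0.26 in the pooled arrays. Without TM175 array 1 and with extract type in the model, the sarcomere list's median was -0.03 (adjusted p = 0.12), and the glycolysis (-0.05, 0.131), antioxidant (-0.05, 0.344) and ion channel lists (-0.11, 0.0704) did not pass either. The hypertrophy and fetal list did not pass in TM175 (median 0.15, 11 of 13 members above 0, adjusted p = 0.0592), and its adjusted p was 0.597 with extract type in the model and an estimated correlation. Without TM175 array 1 and with extract type in the model its median was 0.40 (adjusted p = 1.03e-05 with the preset correlation). Its members Nppa, Nppb, Acta1 and Ankrd1 were low in that array, so this value is no separate support either. The remaining lists did not pass in TM175, with medians of 0.13 for immediate early genes, -0.04 for heat shock, -0.01 for hypertrophic signalling, 0.10 for apoptosis and 0.05 for the circadian clock. Among cell type lists that did not pass, medians were 0.20 for endothelial, 0.12 for smooth muscle, -0.11 for macrophage, 0.16 for red blood cell, 0.05 for atrial, 0.05 for skeletal muscle and 0.16 for adipocyte markers. The 4 sex-linked genes had a median of -0.46. For heat shock and smooth muscle genes median and mean differed in sign, with means of 0.08 and -0.03.

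TM180 was compared with NTG in the same way to describe the severe line. Nppa rose 10.8-fold (4.15 to 28.1, adjusted p = 0.0483), from 732 ± 151 in NTG (SD, n = 3) to 7902 ± 1390 in TM180 (SD, n = 4). Myh7 rose 9.75-fold (6.49 to 14.6, adjusted p = 0.00129) to 3350 ± 635, and Postn 5.04-fold (3.85 to 6.60, adjusted p = 0.00125) to 1046 ± 197. Further large rises were in Tgfb2, a transforming growth factor (3.97-fold, adjusted p = 0.0123), and the fibrillar collagens Col1a1 (3.69-fold, adjusted p = 0.015) and Col3a1 (3.19-fold, adjusted p = 0.0363). The matrix genes Ltbp2 (3.24-fold, adjusted p = 0.0161) and Mfap5 (2.83-fold, adjusted p = 0.0123) rose as well. The Tgfb2 and Col3a1 probe sets were dim, at 25.8 and 36.9 in NTG. Other probe sets of Tgfb2, Col1a1 and Col3a1 lay in the same direction but did not pass. In all, 114 of 22626 probe sets were called, 84 higher and 30 lower, standing for 64 and 21 named genes, and 42 of them differed at least 2-fold.

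Among genes with a single symbol, taken by their brightest called probe set whose arrays did not overlap between the groups, the largest falls in TM180 were in Rgs2 (2.59-fold lower, adjusted p = 0.0184), H2-Aa (2.37-fold lower, adjusted p = 0.0181), Ces1d (2.36-fold lower, adjusted p = 0.02) and Il15, the interleukin-15 gene (2.15-fold lower, adjusted p = 0.0383). A dimmer probe set of H2-Aa had a log2 difference of -1.62, and a called probe set outside this choice fell by 1.96. Hccs, Etfbkmt, a lysine methyltransferase gene, Tmod4 and Fbp2, the muscle fructose bisphosphatase, were 1.99-fold to 2.07-fold lower, with adjusted p between 0.0249 and 0.0408. A brighter second probe set of Rgs2 did not pass without extract type in the model (adjusted p = 0.338) and did with it (log2 difference -1.19 ± 0.15, adjusted p = 0.00251). Nppb was at 2.19-fold (1.1 to 4.36, adjusted p = 0.433) and Acta1 at 2.25-fold (1.08 to 4.70, adjusted p = 0.461), and neither passed. Myh6 was at 0.916-fold (adjusted p = 0.852), Atp2a2 at 0.840-fold (0.733 to 0.964, adjusted p = 0.352) and Pln at 0.954-fold (adjusted p = 0.977). Other probe sets lay at 0.41-fold for Myh6 (0.0321 to 5.23), at 0.763-fold to 0.951-fold for Atp2a2 and at 0.822-fold and 0.856-fold for Pln. None of them passed.

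**Figure D2:**
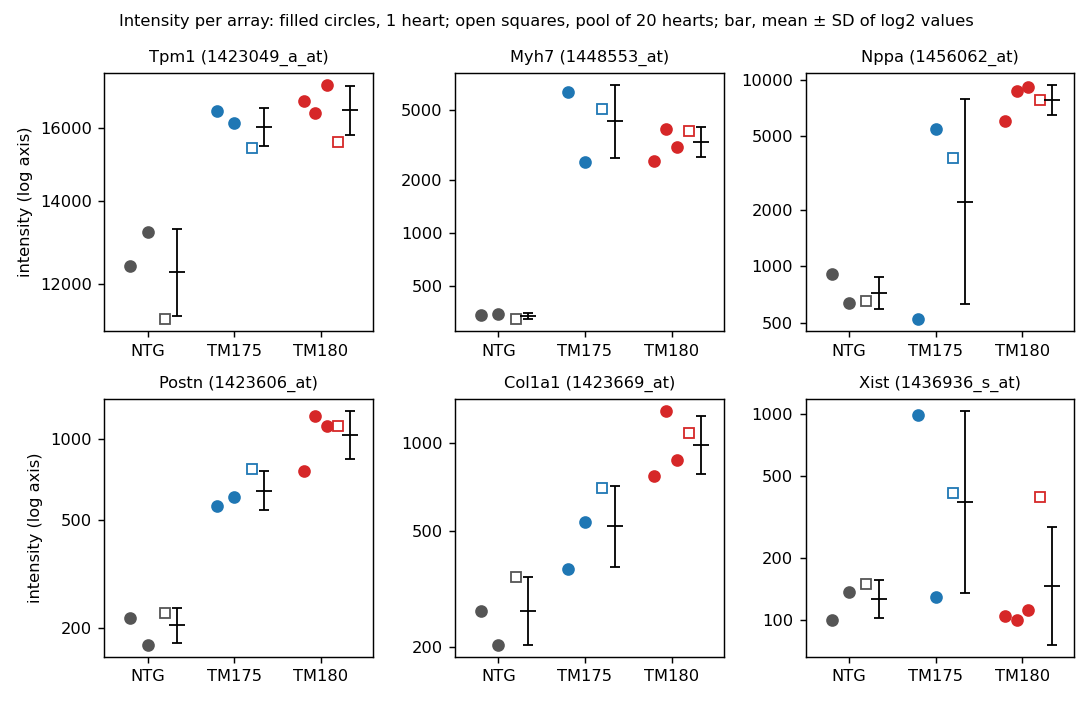
Intensity per array on log axes for 6 genes by genotype; circles are single hearts, squares are pools of 20 hearts, and bars give the mean ± SD of log2 values. Myh7 and Postn lie above all NTG arrays in all 7 transgenic arrays, whereas Nppa in TM175 array 1 (521) lies below the NTG arrays, and Xist is highest there (988).

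With extract type in the model, 454 probe sets were called in TM180, 332 higher and 122 lower, including all 114 of the first model. Timp1, a metalloproteinase inhibitor (log2 difference 1.05 ± 0.20 SE, adjusted p = 0.0216), the growth factor gene Igf1 (0.72 ± 0.12, adjusted p = 0.012) and the immediate early factor Egr1 (0.76 ± 0.13, adjusted p = 0.0126) joined the rises. Acaa2 (-0.71 ± 0.14, adjusted p = 0.0251), Etfdh (-0.61 ± 0.11), Acot1 (-0.46 ± 0.10), Acadm (-0.42 ± 0.09), the calcium channel subunit Cacnb2 (-0.71 ± 0.16), Ttll1 (-1.26 ± 0.23) and Ano10 (-1.13 ± 0.23) joined the falls. For Acaa2 this was a different probe set from that named in TM175, which gave -0.91 in TM180 (adjusted p = 0.0274). The individual arrays alone gave log2 differences of 3.36 for Nppa, 3.19 for Myh7, 2.37 for Postn and 2.03 for Col1a1, and the pooled arrays alone 3.57, 3.55, 2.29 and 1.63. The individual arrays alone gave 44 calls and array weights 754. The count without covariate ranged from 8 without NTG array 1 to 135 without TM180 array 1. It was 39 without NTG array 2, 25 without NTG array 3, 17, 26 and 57 without TM180 arrays 2, 3 and 4, and 62 without TM175 array 2. Of the named genes Myh7 and Postn passed in all 10 fits that left out 1 array, Tgfb2 and Mfap5 in 8, Col1a1, Rgs2 and H2-Aa in 7, Ltbp2 in 6, Etfbkmt and Upk3b in 5, Col3a1, Ces1d, Tmod4 and Mt2 in 4, Nppa, Il15 and Hccs in 3, Gpx3 in 2, and Fbp2 and Hk1 in 0.

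In TM180, 12 of the 25 lists stood apart by camera with the preset correlation, 7 higher and 5 lower. By fry the matrix (adjusted p = 0.00215), fatty acid oxidation (0.00668), hypertrophy (0.0159) and citrate cycle lists (0.0159) passed. So did calcium handling (0.0275), fibroblast markers (0.0323) and the sex-linked list (0.0159), the last of which camera did not call. The extracellular matrix list remained called with an estimated correlation (adjusted p = 0.0342; 8.92e-49 with the preset one). Of its 37 measured genes 15 rose and 31 rose when adjusted over the list alone, with Postn, Col1a1, Ltbp2 and Mfap5 first. All 37 lay above 0, and the median log2 difference was 0.99, or 1.01 with extract type in the model, 0.97 in the individual arrays and 1.00 in the pooled arrays. Its adjusted p with both extract type in the model and an estimated correlation was 0.0968. The hypertrophy and fetal list, of which Nppa and Myh7 rose and 10 of 13 rose when adjusted over the list alone, had a median of 0.87 (adjusted p = 2.98e-14; 0.108 with an estimated correlation). Individual and pooled arrays each gave 0.85 for this list.

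Energy metabolism genes stood lower in TM180. The 24 fatty acid oxidation genes had a median of -0.27, 23 of them below 0 and 7 lower when adjusted over the list alone (adjusted p = 6.25e-12; 0.0541 with an estimated correlation). The individual arrays gave -0.24 and the pooled arrays -0.41. All 36 citrate cycle and oxidative phosphorylation genes lay below 0, at a median of -0.19 (adjusted p = 6.25e-12; 0.108 with an estimated correlation), with none past the threshold alone. The individual arrays gave -0.17 and the pooled arrays -0.20. Glycolysis as a list did not move (median 0.04, adjusted p = 0.783), while the hexokinase Hk1 rose 1.35-fold (adjusted p = 0.0487). In the antioxidant list (median -0.02, adjusted p = 0.802) the plasma glutathione peroxidase Gpx3 and the metallothionein Mt2 each rose 1.80-fold (adjusted p = 0.049 and 0.0363).

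Calcium handling (median -0.10, adjusted p = 0.0174), ion channel (-0.16, 0.0174) and interferon response lists (-0.26, 4.71e-05) stood lower in TM180 with the preset correlation. The interferon list had a median of -0.48 in the individual arrays and 0.03 in the pooled arrays. Immediate early genes (0.18, 0.00843), fibroblast markers (0.34, 2.01e-08), endothelial markers (0.13, 0.0107), smooth muscle markers (0.20, 0.0364) and, at the threshold, heat shock genes (0.15, 0.05) stood higher. With an estimated correlation the adjusted p of these 8 lists lay between 0.108 and 0.673. Col1a1 and Mfap5 rose among the fibroblast markers and are also members of the matrix list. Lists that did not pass in TM180 had medians of 0.01 for the sarcomere and Z disc, 0.05 for hypertrophic signalling, 0.05 for apoptosis, 0.04 for the circadian clock and -0.15 for the sex-linked genes. Medians of the cell type lists that did not pass were 0.03 for macrophage, 0.00 for lymphocyte, -0.10 for red blood cell, -0.01 for atrial, -0.02 for skeletal muscle and 0.10 for adipocyte markers. Median and mean differed in sign for the antioxidant (mean 0.06), atrial (0.09) and skeletal muscle lists (0.01). Among atrial markers Upk3b, a uroplakin gene also used as a mesothelial marker, was 1.80-fold lower in TM180 (adjusted p = 0.0184).

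**Figure D3:**
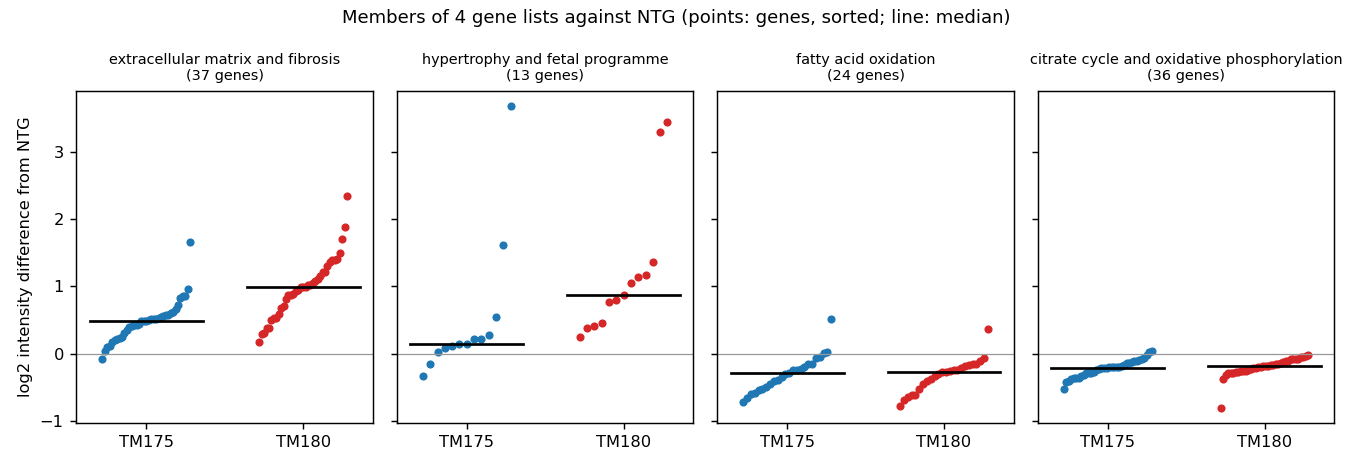
Log2 intensity difference from NTG of each member of 4 gene lists in TM175 and TM180; points are genes sorted within a list and black lines are medians. The matrix list has medians of 0.49 and 0.99 and the fatty acid oxidation list medians of -0.29 and -0.27.

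TM180 was set against TM175 to test whether the severe and the mild line differed. No probe set passed in limma, and 3001 had an unadjusted p under 0.05. With array weights, which ran from 0.309 for TM175 array 3 to 3.24 for TM175 array 2, 2341 passed, more of them lower than higher. The smallest p-values belonged to Alas2, the erythroid heme synthesis enzyme (1.63-fold lower in TM180, adjusted p = 0.136), the sialyltransferase gene St3gal2 (1.93-fold higher, 0.136), the small GTPase gene Rrad (2.19-fold higher, 0.136), Mllt11 (1.74-fold higher, 0.273) and Rras2 (1.57-fold higher, 0.273). A model with extract type called 6 probe sets. Tgfb2 (log2 difference 1.49 ± 0.21 SE, adjusted p = 0.0476), Rrad (1.15 ± 0.14, 0.0388), St3gal2 (0.95 ± 0.12, 0.0388), Mllt11 (0.82 ± 0.12, 0.0487) and Ddx39a (0.64 ± 0.09, 0.0476) were higher in TM180 and Alas2 (-0.70 ± 0.09, 0.0388) was lower. That model called 0 without TM175 array 1. Nppa was 3.52-fold higher in TM180 (1.35 to 9.16, adjusted p = 0.324), Acta1 2.20-fold (1.05 to 4.61, 0.364) and Nppb 1.81-fold (0.910 to 3.6, 0.416), while Myh7 was at 0.764-fold (0.508 to 1.15, 0.505). Myh6 was at 1.03-fold, Atp2a2 at 1.05-fold and Pln at 0.962-fold, with adjusted p of 0.704 to 0.822. The other Atp2a2 probe sets lay between 0.959-fold and 0.983-fold, and the scattered Myh6 probe set at 1.35-fold (0.105 to 17.2).

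As groups, 9 lists differed between the lines by camera with the preset correlation, and none with an estimated one (adjusted p of 0.396 or more). None passed by fry (adjusted p of 0.101 or more). The matrix list was higher in TM180 by a median of 0.47, with 36 of 37 genes above 0 and 20 higher when adjusted over the list alone (adjusted p = 2.7e-17). The hypertrophy and fetal list was higher by 0.65, with 6 of 13 higher when adjusted over the list alone (adjusted p = 4.76e-06). The individual arrays gave medians of 0.54 and 0.72 for these lists and the pooled arrays 0.43 and 0.72. Sarcomere (0.09), glycolysis (0.12), antioxidant (0.18), fibroblast (0.24) and smooth muscle lists (0.22) were also higher, and lymphocyte (-0.20) and red blood cell markers (-0.15) lower. Without TM175 array 1 and with extract type in the model the matrix list kept a median of 0.43 (adjusted p = 9.91e-17) and the hypertrophy list 0.38 (0.000188), and 5 lists were called, each with the preset correlation. The sarcomere (0.04, 0.0775), glycolysis (0.09, 0.0775), antioxidant (0.07, 0.0903) and smooth muscle lists (0.16, 0.0903) did not pass in that fit. Fatty acid oxidation did not differ between the lines at this number of arrays (median -0.02, adjusted p = 0.943), nor did the citrate cycle list (0.03, 0.483). The adjusted p of the lists that did not pass in this comparison lay between 0.0832 and 0.943.

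The calls of the 2 lines overlapped in Myh7 and Postn, both higher, against 0.00743 expected for independent lists and at most 0 in the simulations without covariate. In the model with extract type the lines shared 16 rises, among them Col1a2, Fstl1, Fn1 and Bgn, and 48 falls, among them Acaa2, Decr1, Etfdh, H2-Aa and Hccs. Independent lists would share 0.426 and 0.895, and in 100 simulations of unchanged groups against the same controls the overlap was at most 1. Simulated noise was independent between probe sets, here and without covariate, so overlap among correlated genes was not tested. The shared calls numbered 13 without TM175 array 1. The log2 differences of the 2 lines correlated at 0.54 across probe sets, which are not independent replicates, against a mean of 0.523 in the simulations. Their covariance was 0.0256 against a simulated 0.0098, a difference of 0.0158. The same sign was shared by 62% of probe sets against a simulated 67.5%. In the model with extract type the correlation was 0.508 against 0.535, and 59.8% shared a sign against 67.9%, so that these measures did not exceed the simulations while covariance and overlap did.

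Pooled and individual extracts were compared with genotype in the model to see whether pools stood apart. Of 22626 probe sets 5013 differed, 2263 higher and 2750 lower in pools, and 389 differed at least 2-fold. Crim1, a transmembrane cysteine-rich protein gene (215 in pools against 23.8), the lipid-metabolism receptor gene Ppara (402 against 56.3), Wdr26 (561 against 78.6) and the cytoskeletal gene Palld (760 against 122) were among the largest rises, named here after their values were seen. Of the 13 fibroblast markers 5 were higher in pools (median 0.37), as were 6 of 37 matrix genes (median 0.07), 5 of 17 calcium handling genes (median -0.006) and 3 of 15 endothelial markers (0.18), whereas 3 of 11 lymphocyte markers were lower (-0.17). Other lists had calls both ways, with 5 higher and 2 lower for hypertrophic signalling, 4 and 2 for immediate early genes, and 2 and 3 for fatty acid oxidation. These counts stand beside 5013 of 22626 among all probe sets, and no list was tested here. No hypertrophy, interferon, adipocyte or sex-linked list member differed. The Actb control probe sets read 2998 to 3994 at the 3′ end in the pools and 801 to 1337 in the individual arrays, and the B1 repeat control read 2178 to 3090 against 623 to 1492.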

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

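The tests of unspliced sequence and of sex mix in pools, of 1 array fewer, of a nontransgenic TM175 array 1 and of the cardiomyocyte share were chosen after the result was seen. Xist in the TM180 pool (393.7) lay far from the other TM180 arrays, the nearest of which read 111.4, and the gap made up 0.918 of the range. Of 37 named probe sets tested in the TM180 arrays this was 1, where chance gives about 1 in 20.

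Several gene lists differed between the effects of the lines by camera. In TM180 against TM175 the mean log2 difference was 0.68 (0.677) for the hypertrophy and fetal list, 0.5 for the matrix list, 0.151 for the sarcomere list, 0.159 for glycolysis, 0.168 for antioxidant genes, 0.31 for fibroblast markers and 0.168 for smooth muscle markers. It was -0.198 for lymphocyte markers and -0.277 for red blood cell markers. The adjusted p lay between 2.7e-17 and 0.0314 with the preset correlation and between 0.396 and 0.573 with an estimated one. The real grouping called 9 lists, and 5 of 35 splits of the 7 arrays called as many, with up to 11 in another split, so chance was not excluded.

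Other groupings of the arrays were counted for each comparison. For TM180 against NTG, 1 of 35 splits gave as many calls as the real 114, the highest other being 0. This argues against chance without excluding it, since 35 splits allow no smaller share and some placed both pools on 1 side. For its lists 2 of 35 splits gave as many as 12, the highest other being 13, so chance was not excluded. For TM175 against NTG only 10 splits exist, too few for a share under 0.05. The real split gave 2 calls and 11 lists, as large results came from 2 splits in each case, and the highest others were 2483 calls and 11 lists. The split with 2483 calls set TM175 arrays 1 and 2 and NTG array 2 against both pools and NTG array 1, which points to a structure of the samples. Pools alone do not give it, since the other splits with both pools on 1 side had 0 calls. The 3 arrays set apart had the lowest scores on the first principal component (-31.56, -22.06 and -24.32). With extract type in the model the TM175 count was 195. For TM180 against TM175 all 35 splits gave at least the real 0 calls, the highest other being 1. For pooled extracts 1 of 36 choices of 1 array per genotype reached 5013 calls, the highest other being 88, which argues against chance without excluding it. For the overlap 3 of 100 groupings gave at least 2 shared calls. Those with 960 and 885 set the 3 pooled arrays together as controls. With extract type in the model the lines shared 64 calls, and groupings were not counted for that model.

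The pooled arrays differed from individual arrays of their own genotype, and Xist was higher in the TM175 and TM180 pools (414 and 394) than in 6 of the 7 individual arrays, and 149 in the NTG pool. With each array's Xist intensity as a covariate 95.9% of the calls stayed in the same direction, but TM175 array 1 (988) set most of the spread of Xist, which hardly followed pooling, so a different sex mix stays open. Genes higher in pools had a median genomic length of 35.2 kb against 18 kb for genes lower in pools, a ratio of 1.95 (95% interval 1.70 to 2.20). This is consistent with unspliced or genomic sequence in the pooled extracts, which remains a hypothesis. Handling of the pools as a batch stays open too.

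TM175 had fewer calls than TM180 against NTG in the model without weights (2 and 114), whereas array weights reversed the order, with 5361 and 754 calls. Those weights were 3.24 for TM175 array 2 and 2.92 for NTG array 1, against at most 0.716 for the others of these genotypes. The weighted TM175 comparison therefore rested largely on 1 heart per group. With 1 TM180 array left out at least 17 probe sets were called, which argues against the smaller group as the whole cause. Myh7 in TM175 array 1 was 18.1 times the highest NTG array, which argues against a nontransgenic heart. Myh7 is not the transgene, so this value does not exclude one. From 1 individual and 1 pooled TM180 array, with extract type in the model, at least 91 probe sets were called, against 14 for TM175 without array 1, so the spread of that array is not the whole cause. Since the order depends on the weights, a weaker response of the milder line is not shown and stays open.

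Matrix genes rose in TM180. A larger share of fibroblasts as the whole cause is argued against by the 7 fibroblast markers outside the matrix list, Pdgfra, Tcf21, Dpt, Pcolce, Gsn, Ddr2 and Thy1, with a mean intensity above 50 (Wif1, at 10.9 and a log2 difference of -0.60, was left out), whose median was 0.33 (SD 0.27) against 0.99 for the matrix list. The most abundant, Gsn, differed by 0.32, while Pcolce (0.87) and Dpt (0.59) lay closer to the matrix median, so a larger share of fibroblasts as part of the cause stays open. A smaller share of cardiomyocytes is argued against by the endothelial, smooth muscle and leukocyte lists, of which the highest median was 0.20. Activation of matrix genes within fibroblasts is a hypothesis that the values may suit, and a change of array labelling between genotypes was not tested.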

How the results depend on the processing

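With extract type as a covariate the calls numbered 195 for TM175, 454 for TM180, 6 for TM180 against TM175 and 64 for the overlap. Without TM175 array 1, chosen after seeing the data, they were 14, 484, 0 and 13, and 5 lists differed between the lines. Array weights gave 5361, 754 and 2341 calls, 436 shared and 5 lists for TM175. Individual extracts gave 44 for TM180. The replicate block gave 1 for TM175, 32 for TM180 and 1 shared. Residuals of arrays with the same number correlated between -0.534 and 0.707, but both extremes involved pools. Among individual arrays they ran from -0.113 to 0.485 for the same number and reached 0.663 for different numbers, so pairing by number was not seen. Median centring gave 1 for TM175 and 1 shared. With only the groups compared, hence fewer arrays for the spread, the counts were 0 for TM175, 55 for TM180 and 0 shared. An adjusted p under 0.01, stricter by construction, gave 1, 11 and 1 shared, and 1823 for pooled extracts, where a 1.5-fold minimum gave 1065. With 1 probe set per gene 3 were called for TM180 against TM175 and, counting genes in place of probe sets, 2448 for pooled extracts. Probe sets above the median level gave 1898 for pooled extracts, and 6 lists for TM175 and 3 for TM180 against TM175. Quantile normalization gave 4 lists for TM180 against TM175. With an estimated correlation 0, 1 and 0 lists passed in TM175, TM180 and TM180 against TM175, and with extract type added, also chosen after seeing the data, 0, 0 and 0. Except where the construction is named, the cause was not tested.

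Leaving out each array gave 1 to 2 calls for TM175, 8 to 135 for TM180, 0 to 1 for TM180 against TM175, 1 to 2 shared and 2049 to 6791 for pooled extracts. The lists ranged from 5 to 14, 7 to 12 and 6 to 11. The lowest TM180 count was without NTG array 1.

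Reversals were confined to genes that did not pass. With individual extracts Acta1 in TM175 was -0.097, Pln in TM175 0.004, Xist in TM180 -0.149 and Eif2s3y in TM180 0.04. With the block Xist in TM180 was -0.266 and Eif2s3y 0.078. With array weights Pln was 0.02 in TM175 and 0.002 in TM180, and Myh7 in TM180 against TM175 0.005. With quantile normalization Pln in TM175 was 0.016 and Atp2a2 in TM180 against TM175 -0.082. With median centring Acta1 in TM175 was -0.014. Without TM175 array 1 and with extract type Eif2s3y in TM180 against TM175 was -0.022. Leaving out 1 array, TM175 ranged from -0.183 to 0.888 for Nppb, -0.464 to 0.764 for Acta1 and -0.067 to 0.046 for Pln, and TM180 from -0.266 to 0.395 for Xist and -0.183 to 0.078 for Eif2s3y. The causes were not tested.

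No called list reversed under these alternatives. In the pooled arrays alone, which were not among them, some called lists had medians of the opposite sign. These were the interferon list (0.26 in TM175, 0.03 in TM180) and the smooth muscle list (-0.04 in TM180, -0.01 in TM180 against TM175). Lists that were not called were not counted here, and some changed sign, such as heat shock in TM175, from a median of -0.04 to 0.07 with individual extracts. Of the values of named genes under alternatives other than leaving out an array, 133 in TM175, 246 in TM180 and 155 between the lines kept direction and side of the threshold. Another 5, 36 and 0 no longer passed, and 13, 6 and 9 newly passed. For called lists 96, 121 and 80 stayed and 47, 35 and 37 no longer passed. Signal over background was not measured, and 225 tested probe sets had an unsettled level.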

Other observations

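Both tests of the genes lower in both lines were chosen after the result was seen. With extract type in the model 48 probe sets were lower in both lines, among them those of 38 genes with a single symbol, and without TM175 array 1 the shared falls numbered 9 probe sets, so the count depends on that array. The 38 genes included the mitochondrial genes Etfdh, Acaa2, Decr1, Acad11, Dld, Ndufs4, Mtch2 and Clpx, picked out after their values were seen, with no test of enrichment. Etfdh averaged 1567 in NTG, 947 in TM175 and 1020 in TM180, and Decr1 640, 376 and 388. The class II genes H2-Aa (489, 197 and 203) and H2-Ab1 (371, 178 and 194) were also lower, as were the X-linked neighbours Hccs (801, 386 and 391) and Msl3 (364, 187 and 201). For these 6 genes each transgenic array lay below each NTG array.

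Chromosome segments that differ between the transgenic and the nontransgenic hearts could lower neighbouring genes together. Of the 38 genes, 2 pairs lay within 10 genes of each other, Hccs with Msl3 and H2-Aa with H2-Ab1. In 10000 random gene sets the median was 0 and the highest 6 (permutation p = 0.0534, one-sided), so this stays open. Fewer antigen-presenting cells in both lines could lower class II genes, but the macrophage and leukocyte list had medians of -0.11 in TM175 and 0.032 in TM180. The individual and pooled arrays gave -0.21 and 0.20 in TM175, and -0.01 and 0.13 in TM180. These values argue against a general loss of leukocytes as large as the fall of the class II genes. A smaller loss in the individual TM175 hearts, or a loss of only class II-positive cells, stays open.

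TM175 array 1 had the highest Myh7 of all arrays (6319), while Nppa (521), Acta1 (733), Nppb (952) and Ankrd1 (1841) lay below the lowest NTG arrays (635, 1562, 1328 and 3342). Its Postn read 562 and its Tpm1 16520, both above the NTG arrays. Its Xist of 988 with Eif2s3y of 7.23 may mark a female heart, and its Kdm5d (33.3) was the lowest of all arrays. Its Uty (40.04) lay within the 37.9 to 50.4 of the other individual arrays, which leaves this open. The other 6 individual arrays, with Xist of 99.5 to 136, may be male. Without this array and with extract type as a covariate, TM175 had 14 calls. The pools read 414 in TM175, 394 in TM180 and 149 in NTG, so sex could be mixed in part with genotype. Among individual extracts only, where TM180 and NTG arrays all had low Xist, TM180 had 44 calls.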
